A study of Arabidopsis thaliana with 39 samples.

How the data were processed

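Root RNA of Arabidopsis thaliana (accession Col-0) was measured on 39 whole-transcript expression arrays, in 13 groups of 3. Per the labels' protocols, plants were grown for 10 days with 1 mM phosphate and then moved to new medium, and 100 ng of total RNA per sample was amplified, labelled with biotin and hybridised. The groups are roots at the time of transfer (time 0) and roots after 3, 6 and 9 h in full medium, in medium without phosphate, in medium without iron, and in medium without both. The labels number the replicates of each group from 1 to 3 and do not say that these came from separate cultures, so p-values measure the spread between these samples, which can be partly technical.

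The deposited table holds 1 value per array and row for 28501 rows, with no missing value. Per the submitters' processing notes the tools were Affymetrix Expression Console, Transcriptome Analysis Console and GCRMA, with versions not given in the sources used here. GCRMA corrects background from probe sequence, normalizes across arrays and summarises the probes of a row. The deposited values were taken as log2 because they run from 0.141 to 12.8 with array medians between 3.34 and 3.45. The log base is inferred from that range and is not stated, and every fold below depends on it. All row identifiers are plain numbers that do not tell control rows apart, so all rows were tested. The number of arrays limits the precision.

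Rows were named through the platform annotation given with the series. It gives exactly 1 gene for 16746 rows (58.8%), several for 758 and none for 10997 (38.6%). Symbols of the 1-gene rows were updated through their gene numbers in RefSeq (assembly TAIR10.1, used for names only), where 16601 of them matched. The named part is not a random sample: 16.8% of RefSeq protein-coding genes with a symbol of their own have a 1-gene row, against 85.8% of those known only by locus. A row without a name is given by its transcript cluster number. Of 315 entries in 24 gene lists fixed before the data were examined, 49 have a 1-gene row and 2 more lie on a row with several genes. The other 264, most of the listed phosphate and iron genes among them, are on no row with a gene named, and whether they are among the rows without a name was not determined. For a gene with several rows, the row with the highest mean over the arrays was used.

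All 39 arrays entered 1 linear model with a mean per group (limma 3.58.1 in R 4.3.3, lmFit and eBayes). Each contrast was adjusted with the Benjamini-Hochberg method over all rows and called at an adjusted p under 0.05, with no fold minimum. Contrasts were each deprivation against full medium at each time (9), their means over the times (3), the phosphate by iron interaction averaged over the times (1) and full medium against time 0 (3). Comparisons of the double with the single deprivations, of deprivation effects between times and of the interaction at single times were added after the data had been seen. Lists with at least 3 measured genes (8 of 24, a minimum set after the annotation had been seen) were tested with limma's camera at a preset correlation of 0.01, two-sided, adjusted over 128 tests, with an estimated correlation beside it. Errors of log2 fold changes are standard errors (SE) of the fit, and intervals are 95%.

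The genes named follow a rule fixed before the data were examined. It takes the 5 largest called changes of each sign in every deprivation contrast among 1-gene rows, up to 4 called members of each list, 12 phosphate and iron genes in any case if measured (LPR1 and IMA1 were), the 5 interaction genes of each sign with the lowest p, and the 3 largest called changes of each sign in full medium against time 0 at each time. Not every gene the rule selects is printed. Of its interaction genes, none of which passed, only the interactions of AT3G10585 and PRX52 are given. Other genes, list members without a call over all genes among them, and the rows without a name were chosen after their values were seen.

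No 2 arrays were identical. The closest pair differed by a root-mean-square of 0.299 on the log2 scale, against a median of 0.431 between replicates and of 0.431 between arrays of other groups. Whether the replicate numbers pair the arrays was checked from the correlation of deviations from the group means over all rows: it averaged 0.259 for arrays of other groups with the same number and -0.128 for other numbers, 37 of 39 arrays lay closest to their own number, and the first principal component (21.3% of the variance) separated replicate 3 from replicates 1 and 2. Every pair exceeded 0.1 in 6 of 16 comparisons: no phosphate at 6 and 9 h, no iron at 3 and 6 h, both absent at 9 h and full medium at 3 h against time 0. Over the rows brighter than the median it was 8 of 16, since full medium at 6 and 9 h and both absent at 3 h then passed and no iron at 6 h did not. Both of these sets of rows, and a further set with a minimum mean level, were tried, and all rows were settled on after counts with the replicate block had been seen.

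The alternatives were the replicate block, a fit with the compared groups alone, a filter on rows under the 30th percentile of mean signal, 1-gene rows alone, quantile normalization, a trended robust prior (trended only for the list tests), a log2 change of at least 1, and each array left out in turn. Array quality weights, with and without the block, and leaving out the 2 arrays of lowest weight were added after seeing the data. The test was checked on simulated values with 200 changed rows among 28501, drawn with each row's spread and without any shared replicate effect. For both nutrients absent at 3 h it called 14.9% of changes of 0.5 on the log2 scale, 59.7% of changes of 1 and 95.5% of changes of 2. For the mean over 3 times it called 64.2%, 92.5% and 100%. These shares hold for 200 changed rows and can be lower with fewer.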

Results

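The series followed the root transcriptome of Arabidopsis during the first 9 h after transfer to medium lacking phosphate, iron or both. Each of the 13 groups held 3 arrays, and array medians lay between 3.34 and 3.45 on the log2 scale. The design asks which transcripts respond to each missing nutrient, whether phosphate and iron act together, and what the transfer itself changes. Changes were few between media and many over time.

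**Figure D1:**
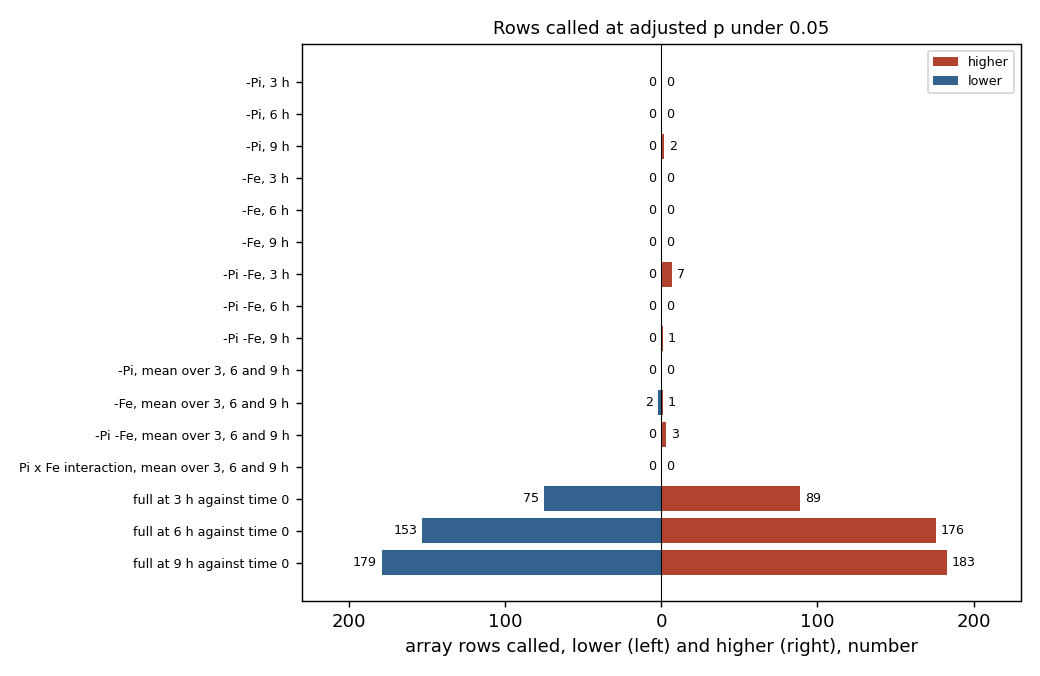
Number of array rows called higher (right, red) and lower (left, blue) at an adjusted p under 0.05 in each of the 16 comparisons, with -Pi and -Fe for medium without phosphate or iron. The deprivation comparisons hold between 0 and 7 rows, and full medium against time 0 holds 164, 329 and 362 at 3, 6 and 9 h.

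Without phosphate, PRX52 (AT5G05340), a class III peroxidase of the cell wall, was the named gene that rose. At 9 h it stood at 5.21 ± 0.82 (SD, n = 3) against 2.14 ± 0.35 in full medium, a log2 difference of 3.07 (SE 0.48, 8.38-fold, limma adjusted p = 0.00734). A fit of these 6 arrays alone did not call it (adjusted p = 0.39) and called 0 rows. PRX52 was higher in each of the 3 deprived arrays than in any full-medium array, but it was picked by this same difference, so that decides nothing. Transcript cluster 13412564, without a name in the annotation used here and chosen after its value was seen, rose by 3.11 (SE 0.49, adjusted p = 0.00734) in the same comparison. Without replicate 2 of the deprived group it rose by 4.07, and without replicate 3 by 2.52 (adjusted p = 0.215). PRX52 differed from full medium by 1.23 (SE 0.28, adjusted p = 0.281) in the mean over the times, which did not pass.

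These were the 2 rows called at 9 h, both higher. At 3 h and at 6 h limma called 0 rows, with 1286 and 1190 rows under an unadjusted p of 0.05, and the mean over the times gave 0 with 1011. Chance alone gives 1425 of 28501. LPR1, the ferroxidase of the root's local phosphate response, differed from full medium by 0.20, -0.08 and 0.03 at 3, 6 and 9 h, and the peptide gene IMA1 (AT1G47400) by 0.03, -0.16 and -0.20. None of these passed. The local phosphate and STOP1 list, with 4 of 13 genes measured, had a mean log2 difference of 0.37 at 9 h (camera adjusted p = 0.0593, and 0.392 with an estimated correlation). In it the aluminium-activated citrate transporter MATE (AT1G51340) stood at 0.97 and RAE1 at 0.38. None of the 4 was called over all genes, nor when adjusted over the list alone. The nitrate list, with 3 of 16 genes measured, had a mean of 0.41 at 3 h. Its camera adjusted p was the same (0.0593, and 0.268 with an estimated correlation). The count at 9 h fell to 0 when replicate 1 or 3 of either group was left out and was 11 without replicate 2 of the deprived group. The mean over the times gave 6 without replicate 3 of full medium at 6 h and 4 without replicate 2 of the deprived group at 9 h.

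Without iron, AT1G04770, a relative of the sulfur-deficiency-induced gene SDI1, rose. Its mean difference over the times was 0.85 (SE 0.15, 1.80-fold, adjusted p = 0.0303). At 9 h it stood at 5.36 ± 0.31 (SD, n = 3) against 3.91 ± 0.19, a difference of 1.45 (SE 0.26, adjusted p = 0.112) that did not pass alone. Transcript clusters 13433000 and 13541395, both without a name here and chosen after their values were seen, fell in the mean by 0.96 (SE 0.16) and 0.88 (SE 0.15), each with adjusted p = 0.0303. These 3 rows were the calls of the mean, 1 higher and 2 lower. At 3, 6 and 9 h limma called 0 rows, with 945, 1075 and 675 rows under an unadjusted p of 0.05. Leaving out 1 array gave 0 rows for the mean when it was replicate 1 or 3 of full medium at 9 h, replicate 2 of full medium at 3 or 6 h, or replicate 2 of the deprived group at 6 or 9 h. It gave 1 row when it was replicate 3 of full medium at 3 h, replicate 1 of full medium at 6 h, replicate 1 of the deprived group at 3 h or replicate 3 of the deprived group at 9 h, and 7 rows without replicate 3 of full medium at 6 h. A fit of the compared groups alone called 0 rows for the mean (adjusted p = 0.239 for AT1G04770 and 0.336 for both clusters). AT1G04770 lost its call without 12 of the 18 arrays, taken 1 at a time (adjusted p from 0.0649 to 0.136).

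Iron-regulated genes with a name showed no call over all genes. In the bHLH Ib and PYE list, with 6 of 19 genes measured, IMA2 (AT1G47395) stood 1.01 above full medium at 9 h (adjusted p = 0.0195 over the list alone), BHLH101 at 0.03, PYE at -0.12 and BTSL1 (AT1G74770) at 0.03. IMA1 differed by 0.17, 0.05 and 0.00 at 3, 6 and 9 h. Of the FIT list 2 of 18 genes were measured, the coumarin hydroxylase S8H (AT3G12900) and BGLU42, at 0.21 and 0.07 at 6 h. The peroxidase list, 5 of 10 measured, had a mean of 0.59 at 3 h (adjusted p = 0.0593, and 0.4 with an estimated correlation). LPR1 stood at 0.28, 0.09 and 0.30. MATE was lower by 1.27 at 6 h when adjusted over its list alone (adjusted p = 0.0307), and also in the mean (0.0295), with no call over all genes. In full medium at 6 h MATE was itself 1.20 above time 0 (limma adjusted p = 0.0215 over its list alone, 0.285 over all genes). The difference at 6 h is thus set against a raised level in full medium. The count at 9 h was 1 without replicate 1 of the deprived group.

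With both nutrients absent, 7 rows rose at 3 h and none fell. Array quality weights, chosen after the data were seen, called 51 higher and 26 lower, and 29 and 8 with the replicate block as well. Without the block, replicates 1, 2 and 3 had weights of 2.34, 0.875 and 0.746 in the deprived group. In full medium at 3 h the weights were 0.682, 1.98 and 0.753. The weighted comparison therefore leans on 1 array of each group, with different replicate numbers. AT2G18193, an AAA-type ATPase, reached 4.50 ± 1.4 (SD, n = 3) against 1.98 ± 0.17, a log2 difference of 2.52 (SE 0.41, 5.73-fold, limma adjusted p = 0.00995). That SE is pooled over all 13 groups and does not reflect the wide spread of these deprived arrays. The full-medium level lay near the first quartile of those arrays (1.66 to 1.71). The difference was 1.79 without replicate 2 of the deprived group (adjusted p = 0.163) and 3.22 without replicate 3 (2.78e-05). AT4G08555 rose by 1.82 (SE 0.31, adjusted p = 0.0130), AT5G22140, of an oxidoreductase family, by 1.06 (SE 0.17, adjusted p = 0.00995), and the leucine-rich repeat receptor kinase AT5G25930 by 1.00 (SE 0.18, adjusted p = 0.0242). The other 3, clusters 13359915, 13493553 and 13475311, have no name here, were chosen after their values were seen, and rose by 1.66, 1.61 and 1.14. At 6 h limma called 0 rows, with 850 under an unadjusted p of 0.05, and at 9 h it called cluster 13491556, higher by 0.85 (SE 0.13, adjusted p = 0.00706). A fit of the compared groups alone called 2 rows at 3 h and 0 at 9 h. It kept AT4G08555 (adjusted p = 0.0428) and not AT2G18193 (0.999), AT5G22140 (0.564) or AT5G25930 (0.627). The 3 clusters at 3 h were not called in it either, with 0.917, 0.627 and 0.404, nor was cluster 13491556 (0.342). The filter on dim rows removed the row of AT4G08555, so this gene was not tested there. With each of the 6 arrays left out in turn, AT4G08555 lost its call 5 times (limma adjusted p from 0.0716 to 0.191). AT2G18193, AT5G22140 and AT5G25930 lost theirs 4 times each. Quantile normalization ended the calls of clusters 13359915 and 13475311 (0.0682 each).

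Averaged over the times, 3 rows rose, and 5 with the replicate block. AT5G38200, at 0.58, was called with the block (limma adjusted p = 0.0467) and not without it (0.196). Its mean difference was about as large without phosphate alone, at 0.56, and was -0.56 without iron alone. Neither was called (limma adjusted p = 0.281 and 0.205 without the block, 0.118 and 0.0537 with it). Of the 3, AT5G22140 was higher by 0.60 (SE 0.10, adjusted p = 0.0185), cluster 13493553 by 1.01 (SE 0.15, adjusted p = 0.00448) and cluster 13540561 by 0.78 (SE 0.14, adjusted p = 0.0390). In a fit of the compared groups alone only cluster 13540561 kept its call (0.0159), against 0.193 for AT5G22140 and 0.0795 for cluster 13493553. With each of the 18 arrays left out in turn, cluster 13540561 lost its call 14 times, AT5G22140 8 times and cluster 13493553 0 times. Without the 2 arrays of lowest weight, chosen after the data were seen, AT5G22140 and cluster 13540561 were not called (0.117 and 0.158). Cluster 13493553 stood 0.73 above full medium in the mean without phosphate alone (adjusted p = 0.281). LPR1 differed by 0.41, -0.10 and 0.15 at 3, 6 and 9 h and IMA1, on its dim row, by 0.22, -0.15 and 0.01, with no call. The dehydration gene LTI30 stood at 0.94 at 3 h and 0.62 in the mean, without a call over all genes. It passed when adjusted over its list alone, with 3 of 8 genes measured (adjusted p = 0.0155 and 0.00539). So did the peroxidase gene PER71 (AT5G64120), lower by 0.82 in the mean (0.033). The shoot marker RCA stood at 0.66 and LHCB4.1 at 0.44 at 3 h, neither called. At 3 h the count was 0 without replicate 1 or 2 of the deprived group or replicate 3 of full medium, 1 and 3 without replicates 1 and 2 of full medium, and 19 without replicate 3 of the deprived group. At 9 h it was 0 without replicate 1 or 3 of full medium or replicate 2 of the deprived group, and 2 without replicate 3 of the deprived group. The mean over the times called 1 row when the array left out was replicate 1 of full medium at 3, 6 or 9 h, replicate 2 of full medium at 9 h, replicate 1 of the deprived group at 3 h, or replicate 2 of the deprived group at 6 or 9 h. It called 5 without replicate 1 of the deprived group at 6 h, 7 without replicate 3 of full medium at 6 h and 10 without replicate 3 of the deprived group at 3 h.

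**Figure D2:**
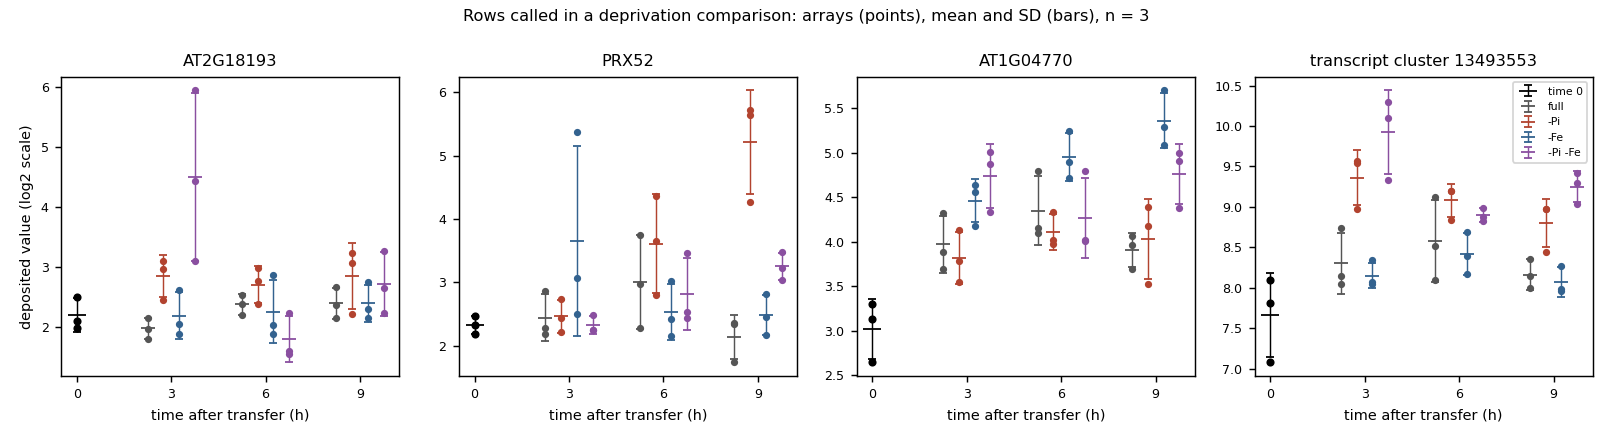
Deposited values on the log2 scale against hours after transfer for AT2G18193, PRX52, AT1G04770 and transcript cluster 13493553. Points are arrays, dashes and bars the mean and SD of 3, with time 0 in black, full medium in grey, -Pi in red, -Fe in blue and both absent in purple. AT2G18193 reaches 4.50 with both absent at 3 h and PRX52 5.21 without phosphate at 9 h.

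Set against the single deprivations at 3 h, the double deprivation called 6 rows higher than no phosphate and 6 higher than no iron. With the replicate block the comparison with no iron at 3 h called 13, of which 12 were higher and 1 lower. At 6 h the comparisons with no phosphate and no iron called 0 and 0 rows. At 9 h they called 0 and 1, and 0 and 0 with the block. The double-deprived arrays at 3 h are those that picked the genes named below, so these comparisons are not independent of that choice. At 3 h AT5G22140 was among both, by 1.06 (SE 0.17, limma adjusted p = 0.0159) and 0.96 (SE 0.17, adjusted p = 0.0264). AT5G25930 exceeded no phosphate 2.47-fold (adjusted p = 0.0011) and did not pass against no iron (0.958). AT2G18193 exceeded no iron by 2.31 (SE 0.41, adjusted p = 0.0217) and no phosphate by 1.65 (adjusted p = 0.396), which did not pass. The interaction of phosphate and iron, averaged over the times, gave 0 rows in limma, with 672 under an unadjusted p of 0.05. Its lowest unadjusted p among named genes was 0.000266, for AT3G10585 (0.37, SE 0.09). PRX52 had an interaction of -1.32 (SE 0.39, unadjusted p = 0.00219). Both had an adjusted p of 1, so neither passed. At 3, 6 and 9 h taken alone the interaction also gave 0 rows, with 1121, 1147 and 599 under 0.05.

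In full medium against time 0, the DnaJ-type chaperone gene AT1G56300 rose most among named genes. It went from 3.66 ± 0.19 (SD, n = 3) to 6.77 ± 0.41 at 3 h and 7.41 ± 0.36 at 6 h, differences of 3.11 and 3.75 (SE 0.26 each, adjusted p = 2.39e-09 and 1.53e-11). The cation exchanger gene CHX16 rose by 2.62 and 2.03 at 6 and 9 h, and the cold-regulated gene AT4G33980 by 1.57, 2.92 and 3.21 at 3, 6 and 9 h. CHX16 was also called at 3 h, with rises of 2.06 to 2.32 over the alternatives (limma adjusted p up to 0.0201). AT1G33840 rose by 2.09 at 3 h and AT2G23910 by 2.74 at 9 h. The transcription factor gene bZIP58 fell by 2.56 at 6 h and by 2.97 at 9 h (SE 0.37 each, adjusted p = 5.83e-05 and 3.9e-06), from 6.60 ± 0.69 at time 0 to 3.64 ± 0.32. AT4G15430 fell by 1.96 and 1.89 at those times, AT1G64500, of a glutaredoxin family, by 1.51, 1.79 and 1.88 at 3, 6 and 9 h, SIS by 1.60 and AT5G66650 by 1.45 at 3 h, and AT3G53980 by 2.15 at 9 h.

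In all, 164 rows were called at 3 h (89 higher, 75 lower), 329 at 6 h (176 and 153) and 362 at 9 h (183 and 179). At least 1 of the times called 507 rows, of which 247 have exactly 1 gene. Among fixed lists, the clock gene GI rose by 1.08, 1.32 and 1.01 (adjusted p = 0.00257, 6.82e-05 and 0.0024), the 1 gene of 13 measured in its list. LPR2 rose by 1.02 and 0.92 at 6 and 9 h. Of the auxin list 7 of 16 genes were measured, with mean differences of -0.57, -0.39 and -0.53. Camera called it lower at 3 and 9 h (adjusted p = 0.0215 at both, and 0.268 at both with an estimated correlation) and not at 6 h (0.0856). Its amido synthetase gene GH3.5 (WES1) fell by 0.95 at 3 h and by 0.76 at 9 h and was the 1 member called over all genes at either time, while 2 members were lower at each when adjusted over the list alone. GH3.3 stood at -1.18, -0.87 and -0.86 and passed over the list alone at 3 h (adjusted p = 0.0244), without a call over all genes (0.262 at 3 h). The list was not called at 3 h without replicate 2 of time 0 (adjusted p = 0.12) or replicate 3 of full medium at 3 h (0.0984), nor at 9 h without replicate 2 of time 0 (0.126) or replicate 1 of full medium at 9 h (0.0812). The shoot marker RCA stood at -0.29, -0.55 and -0.47 and LHCB4.1 at 0.22, 0.34 and 0.25, with no call. In the nitrate list HHO2 (AT1G68670) fell by 0.44 at 6 h and by 0.62 at 9 h, which passed over the list alone (adjusted p = 0.0446 and 0.00309) and not over all genes.

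With the replicate number as a block, 274 rows were called at 3 h, 137 in each direction, and all 164 were among them. The block called 476 at 6 h and 555 at 9 h. Without replicate 1 of time 0 the counts were 63, 168 and 201 at 3, 6 and 9 h, and without replicate 3 of time 0 they were 99, 202 and 211. Leaving out replicate 1 of full medium gave 69 at 3 h and 213 at 9 h, replicate 2 gave 217 at 9 h, and replicate 3 gave 195 at 6 h and 202 at 9 h. A fit of the compared groups alone called 10, 81 and 195. At 3 h it did not call AT1G33840, SIS, AT1G64500 or AT5G66650 (adjusted p = 0.279, 0.463, 0.276 and 0.252), nor AT1G64500 at 6 h (0.0729) or AT3G53980 at 9 h (0.106). Among named genes, AT1G33840 at 3 h was no longer called without replicate 1 or 3 of time 0 (adjusted p = 0.25 and 0.207) or without replicate 1, 2 or 3 of full medium (0.0869, 0.0765 and 0.146). SIS at 3 h was not called without replicate 1 or 3 of time 0 (0.347 and 0.0804) or replicate 1 of full medium (0.379), nor AT1G64500 at 3 h (0.0682, 0.069 and 0.0869 for the same arrays). AT3G53980 at 9 h was not called without replicate 1 or 3 of time 0 (0.131 and 0.116) or of full medium (0.115 and 0.0921).

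**Figure D3:**
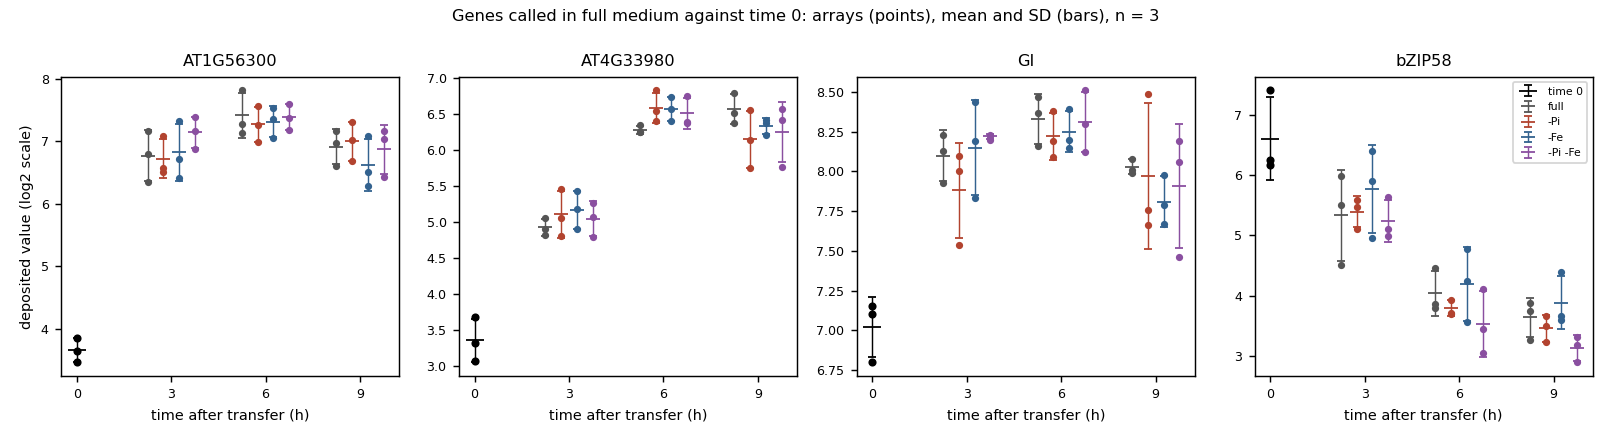
Deposited values on the log2 scale against hours after transfer for AT1G56300, AT4G33980, GI and bZIP58, with arrays as points and the mean and SD of 3 as dashes and bars, coloured by medium, time 0 in black. In full medium AT1G56300 rises from 3.66 to 7.41 at 6 h and bZIP58 falls from 6.60 to 3.64 at 9 h.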

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

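The tests of explanations, of other splits and of differences between times in this part were chosen after the results were seen. Of the 16 contrasts used here, 9 compare a deprivation effect between times, 4 are the interaction, in the mean and at each time, and 3 compare full medium between times. Direct comparisons of the double with the single deprivations are not among them. Read for 36 named genes and transcript clusters, 3 differences passed, in 2 of the contrasts. The cold-regulated gene AT4G33980 was higher in full medium at 6 h than at 3 h by 1.36 (SE 0.21, limma adjusted p = 0.0019) and at 9 h than at 3 h by 1.64 (SE 0.21, adjusted p = 1.88e-05). Transcript cluster 13541395, without a name here, went from 3 to 9 h in full medium by -1.32 (SE 0.26, adjusted p = 0.0239). No deprivation effect of a named gene differed between times at an adjusted p under 0.05, and the lowest such value was 0.113, for cluster 13491556 with both nutrients absent at 9 h against 3 h.

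The 13 deprivation comparisons gave fewer rows under an unadjusted p of 0.05 than the 1425 that chance gives, in each of them, with a median of 1011. With the replicate number as a block the median was 1271 and 5 of the 13 exceeded 1425. With array quality weights it was 1563. Both changes are consistent with a spread that is shared by arrays of the same number, or uneven between arrays, and that may hide small effects. Simulated data gave calls for 59.7% of changes of 1 on the log2 scale at 3 h with both nutrients absent. They kept the size of each row's spread but did not share it between arrays, so they do not show how much it hides. They also held 200 changed rows, where the data called 7, which makes an adjusted p under 0.05 easier to reach.

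All 7 of the 7 rows that rose with both nutrients absent at 3 h had every deprived array above every full-medium array, but these rows were picked by this same difference, so 1 array as the source cannot be told apart this way. All 7 were also called with the replicate block, but every group holds each number, so the block leaves the differences between groups as they are, and a spread shared by a number cannot be told apart this way. Green tissue stays open: 2 of 15 shoot markers were measured, their median difference was 0.55 and neither passed, so some green tissue may be part of the pattern. Over all arrays RCA had a mean of 6.98, at the 93.8th percentile of rows, and LHCB4.1 of 5.18, at the 74.8th. Another split of these 6 arrays called 15 rows, so 2 of the 10 splits called at least 7, and 10 splits are too few for a share under 0.05. Leaving out replicate 1 or 2 of the deprived group, or replicate 3 of full medium, left 0 calls. The log2 difference of AT2G18193 was then 2.55, 1.79 and 2.44 and that of AT4G08555 1.87, 1.70 and 1.77, against 2.52 and 1.82 with all arrays. Without replicate 3 of the deprived group AT2G18193 stood at 3.22, so single arrays carry part of its change. None of the other 6 rows moved by over 1.5 times when 1 array was left out, and fewer arrays alone can end a call.

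Of the 362 rows called at 9 h against time 0, 100% had groups that do not overlap. They too were picked by this difference, so a single array as the source of part of them cannot be told apart by it. Leaving out 1 array left between 201 and 393 calls. The 2 shoot markers, RCA lower and LHCB4.1 higher, differed by 0.88 in their change at 6 h. The SE of 0.96 treats them as independent although they share arrays, so it does not measure the spread of that difference. Neither marker was called, so a change in green tissue cannot be told apart with them. The hour of the day may contribute as well as the move to new medium. The hour of harvest is not given in the sources used here, each time was sampled in 1 group per medium, and 1 clock gene of 13 was measured, so these cannot be told apart.

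Other splits of the same arrays were run for each count. A count of 0 is reached by every split, so for those counts the splits decide nothing. Comparisons of 3 with 3 arrays have 10 splits, too few for a share under 0.05. Against time 0 the real counts of 164, 329 and 362 met 1, 1 and 0 as the highest other, and 1 split of 10, the real one, reached each. Where the replicate numbers pair the arrays, 4 of the 10 splits, the real one included, part all pairs and the remaining 6 keep 2 pairs together. Among the splits that part all pairs the highest other was 0 in full medium at 3 h, without phosphate at 9 h, without iron at 3 and 6 h and with both absent at 9 h, and 1 without phosphate at 6 h. Without phosphate at 9 h the real 2 met 1, and with both absent at 9 h the real 1 met 0, again 1 of 10 each. The counts of 0 at single times were reached by 10 of 10 splits by construction, with highest others of 0 and 1 without phosphate at 3 and 6 h, of 9, 0 and 0 without iron at 3, 6 and 9 h, and of 2 with both absent at 6 h. For the means, 100 splits were used, which mix the replicate numbers, and 100 more that exchange media only among arrays of the same time and number. With both absent the real 3 was reached by 2 and by 1 of 100, a share under 0.05 for this mean taken alone. That share is not adjusted over the comparisons, and another split called 19 (1 among those within a number). It is therefore weak ground against chance. Without iron the real 3 was reached by 5 and by 2 of 100, and another split called 180 (36 within a number), so chance is not excluded. The counts of 0 without phosphate and for the interaction were reached by 100 of 100 of either kind, again by construction, with highest others of 2 and 30 (1 and 1 within a number). The 180 without iron, the 30 for the interaction and the 19 with both absent are each the highest of the splits that mix the numbers. The median of those other splits was 0 in each case. A single highest count does not show whether the arrays hold a structure other than the media. Among splits within a number the highest others were 36, 1 and 1, so the numbers may account for part of these counts.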

How the results depend on the processing

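Array quality weights, with or without the block, and leaving out the 2 arrays of lowest weight (no phosphate at 3 h and both absent at 9 h, replicate 2 each) were chosen after seeing the data. With the replicate block the mean with both absent gave 5 rows instead of 3, full medium at 3 h 274 instead of 164 and at 9 h 555 instead of 362. No other count of the 16 planned comparisons changed by over 1.5 times: 476 at 6 h, 3 and 9 for no phosphate at 9 h and both absent at 3 h, 4 for the mean without iron, 1 for both absent at 9 h, and 0 where 0 was called before. In these 16, every row called without the block was called with it. Among the comparisons added later, both absent against no iron gave 13 instead of 6 at 3 h (12 higher, 1 lower) and 0 instead of 1 at 9 h, full medium at 9 h against 3 h gave 66 instead of 33, and against time 0 at 9 h there were 552 instead of 364 without phosphate and 774 instead of 495 with both absent. Fits of the compared groups alone use fewer arrays and only the spread of those groups. They gave 0 without phosphate at 9 h and 2 and 0 with both absent at 3 and 9 h. For the means without phosphate, iron and both they gave 1, 0 and 1, and against time 0 10, 81 and 195. The setting with 1-gene rows alone removes rows without a name or with several genes. Its counts were 1 without phosphate and 0 with both absent at 9 h, and 1 and 1 for the means without iron and with both absent. Against time 0 they were 67, 135 and 157. Of the rows called in the main fit of these comparisons, 1, 0, 1, 1, 72, 152 and 171 have exactly 1 gene. The removed rows therefore account for most of the drop. A log2 change of at least 1 left 0 with both absent at 9 h, 0 and 1 for the means without iron and with both absent, and 91, 184 and 208 against time 0. The filter on dim rows gave 0 with both absent at 9 h, since it removed the row called there, cluster 13491556. Array quality weights gave 1 and 5 without phosphate at 3 and 9 h, 4 without iron at 9 h, 77 (51 higher, 26 lower) and 2 with both absent at 3 and 9 h, 8, 7 and 15 for the means without phosphate, iron and both, and 571 for full medium at 9 h. With weights and block these were 5 without phosphate and 3 without iron at 9 h, 37 (29 higher, 8 lower) with both absent at 3 h, 9, 11 and 20 for the means and 793 for full medium at 9 h. Without the 2 arrays of lowest weight, both absent gave 0 at 9 h and 1 in the mean. Leaving out 1 array gave 0 to 11 without phosphate at 9 h, 0 to 1 without iron at 9 h, 0 to 19 and 0 to 2 with both absent at 3 and 9 h, 0 to 6, 0 to 7 and 1 to 10 for the means without phosphate, iron and both, and 63 to 212, 168 to 338 and 201 to 393 against time 0. The list tests called 2 of 128, 0 with an estimated correlation, 9 with the dim filter, 5 with quantile normalization, 4 with the compared groups alone, 9 with weights, and 0 to 12 with 1 array left out. Where no construction is named, the cause was not tested. Direction was followed for the rule's genes in the comparison that named them, and for rows called in a deprivation against full medium. None called there changed direction under any alternative that kept its row. Other called genes and comparisons were not followed.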

Other observations

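The genes in this part were chosen after their values were seen. In full medium against time 0, the pyruvate decarboxylase gene PDC2 was higher by 2.01 at 6 h and 1.91 at 9 h (limma adjusted p = 1.27e-05 and 2.55e-05), and DPE1, the plastid disproportionating enzyme of starch breakdown, by 0.89, 1.20 and 1.16 at 3, 6 and 9 h. The glutathione reductase gene GR1 fell by 1.20 at 6 h and by 1.06 at 9 h. AT5G15950, an S-adenosylmethionine decarboxylase gene of polyamine synthesis, fell by 0.86, 1.52 and 1.59 at 3, 6 and 9 h. The Dof-type factor gene AT1G26790 fell by 0.83, 0.70 and 0.91. The stress-related factor gene DREB2C was higher by 1.42 and 1.54 at 6 and 9 h.

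The rows that changed most over time have no name in the annotation used here. Cluster 13405973 went by -3.38, -4.79 and -5.37 at 3, 6 and 9 h (adjusted p = 1.08e-15 at 9 h), cluster 13361823 by -4.15, -4.81 and -4.78, cluster 13350088 by 3.80, 4.28 and 3.69, and cluster 13419281 by 1.41, 4.14 and 5.37. Against time 0 at 9 h, 364 rows were called without phosphate, 385 without iron and 495 with both absent, beside 362 in full medium. These counts share the arrays of time 0 and were not tested against each other. Of 35 gene families grouped by symbol, tested with camera in 6 contrasts, 0 of 210 tests passed, with a lowest adjusted p of 0.116.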
